A study of Mus musculus with 16 samples.

How the data were processed

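Poly(A) RNA was measured by RNA-seq in germs of the mouse first molar, the tooth primordia dissected from embryonic jaws. The 16 libraries were labelled as 8 of the upper and 8 of the lower first molar, 1 of each at every step of 0.5 days from embryonic day 14.5 to 18.0. Per the labels, each library pooled the left and right germ of a single wild-type male CD1 embryo, and the upper and lower libraries of a stage came from the same embryo. CD1 is an outbred laboratory strain. Libraries were made with a TruSeq V2 poly(A) kit, which does not mark strand, and were sequenced as 100 bp read pairs, per the labels' protocols.

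The authors deposited a table of whole-number counts per gene symbol for each library, with no normalization. Per the submitters' processing notes, Bowtie2 2.0.2, TopHat2 2.0.6 and HTSeq 0.5.3p9 were used with the mouse genome build mm10. The annotation, the strand setting and whether a count is a read or a read pair are not given in the sources used here. Because strand is not marked, overlapping and antisense genes such as Dlx6 and Dlx6as1 could not be told apart with certainty, and near-identical copies such as the globin genes, keratin genes and histone genes could share or lose reads. Each table held 23337 genes and 5 summary lines, and the summary lines were kept out of library sizes and tests. The share on no annotated feature was 12.6% to 15.1%, and 0.955% to 1.15% was ambiguous between genes.

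The deposited gene counts totalled 33146758 to 44565205 per library, so that a gene at 0.269 CPM (counts scaled to a common library total) rested on 10 counts at the median depth. No pair among the 120 pairs of libraries was identical, and the most similar pair differed at 18027 genes. Counting error is small for well counted genes, where the spread between libraries sets the precision. It is large for named genes near 0 in a label. Over the 8 libraries labelled upper Crct1 had 4 counts, Psca 36, Ddn 49 and Cnfn 54. Crct1 and Psca were at 0 in 4 of 8. An exact 95% Poisson interval, which covers counting error only, is given for the lowest of these.

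Genes were kept where at least 2 libraries reached 0.269 CPM, the value of 10 counts at the median depth, which left 16287 genes. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, the quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). The standard error of a log2 value is its size divided by the square root of F. The tooth difference was fitted over all 16 libraries with a natural spline of the labelled stage with 3 degrees of freedom. The stage trend was a linear slope per labelled embryonic day, fitted in the 8 libraries of each tooth label alone. The interaction was the labelled upper slope minus the labelled lower slope, added to the model of the tooth difference. Log2 CPM used a prior count of 2. The developmental offset regressed, in each individual, the log2 difference between the labelled teeth on the stage slope across the genes that trended in the same direction in both labels, with slopes from the other 7 individuals, and the mean over 8 individuals was tested with an exact two-sided sign-flip permutation test.

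The tests, samples, covariates, alternatives, gene lists and naming rule were fixed before the data were examined. The 28 gene lists covered dental epithelium, dental mesenchyme, enamel knot signals with other knot genes, ameloblast and enamel matrix, odontoblast and dentin matrix, bone and osteoblast, osteoclast, cartilage, skeletal muscle, neuron, Schwann cell, endothelium, erythroid cell, macrophage and leukocyte, oral cornifying epithelium, maxillary arch and palate, mandibular arch, cell cycle, the Wnt, Bmp, Fgf, Hedgehog, Eda, Notch, and activin and Tgfb pathways, basement membrane, immediate early and heat shock genes, and hypoxia and glycolysis. Lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison, and again with an estimated correlation. Named genes had a mean count of at least 50. For the tooth difference they were the 10 with the largest fold in each direction among genes past the threshold with the same sign in all 8 individuals. For the stage trend they were the 10 with the steepest mean slope in each direction among genes past the threshold in both labels with the same sign. For the interaction they were the 5 with the smallest p in each direction. Up to 4 members stand for each list, models without a symbol and small RNAs were skipped, and Xist with 4 Y-linked genes was a sex check. Nkx2-3 lies outside the lists and was chosen after its values were seen. Hbb-b1, Hbb-b2 and Alas2 are given for the tooth difference beyond this rule, also after their values were seen. Some genes that met these rules are not reported here.

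Embryo, stage and individual are the same factor here, with 1 library per tooth label and stage, so a p-value measures scatter about a smooth curve between embryos. The labels pair the teeth of an embryo. After a linear stage term, the residuals of labelled pairs correlated at 0.074 to 0.302 across genes, with 7 of 8 over 0.1, and 3 of 8 correlated best with their own partner. The file names also give a flow cell and a lane: all libraries labelled upper ran on 1 flow cell and all labelled lower on another, and the lanes split each label into its first 4 and last 4 stages. No term could separate flow cell from tooth label.

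Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter beyond a count above 0, the CPM cutoff in at least 8 libraries, an early/late step, leaving out each individual, the individual as a block, linear stage, a test against a fold of 1.5, a quadratic curve, and other gene sets for the offset and the components. A fit without individuals 1 and 2 and slopes within each lane of a label were added after seeing the data. The fits were tested on simulated counts with 100 genes changed by each of 2 sizes among 16287. For the tooth difference 78 of 100 genes were recovered at a log2 size of 0.5 and 99 at 1. For the labelled upper slope 95 and 100 were recovered, for the labelled lower slope 94 and 100, and for the interaction 91 and 100. The sizes of the slopes and the interaction were per day, so they do not compare with the tooth difference. Changed genes had a mean count of at least 50, and the simulation held no other stage curve and no alternation between individuals. The spread of each simulated gene came from the fitted trend with abundance, so none had a spread of its own. Recovery in the real data may therefore be lower. False calls made up 3.48% to 5.34% of the calls. Positions are 1-based on GRCm38.p6, the same build as mm10, matched by gene symbol.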

Results

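The transcriptome of the first molar germ was followed through 8 embryonic stages 0.5 days apart, with 8 libraries labelled upper and 8 labelled lower. The comparisons ask which genes differ between the upper and lower molar, which change as the germ develops, and whether the teeth change alike. Gene counts ran from 33146758 to 38584429 per library in the libraries labelled upper and from 35918529 to 44565205 in those labelled lower.

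A known marker gene of the upper jaw varied more inside each tooth label than between the labels. Pou3f3 (chromosome 1, 42695768 to 42700210), a transcription factor gene of the maxillary arch, measured 6.45 to 10.1 CPM in labelled upper individuals 1, 3, 5 and 7 and 109.5 to 131.5 CPM in individuals 2, 4, 6 and 8. The libraries labelled lower alternated the same way, with 4.45 to 5.46 CPM in individuals 1, 3, 5 and 7 and 60.1 to 86.2 CPM in the others. Nkx2-3 (chromosome 19, 43612325 to 43615892), a homeobox gene chosen after its values were seen, ran opposite to Pou3f3. It measured 39.4 to 56.2 CPM in labelled upper individuals 1, 3, 5 and 7 and at most 0.0905 CPM in the others, against 19.2 to 31.5 and at most 0.112 CPM among the libraries labelled lower. Neither gene passed the test for the labelled tooth difference (adjusted p = 0.525 for Pou3f3 and 0.617 for Nkx2-3, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the individual as a block both were higher in labelled upper (adjusted p = 3.72e-05 and 0.00203 in the same test). The log2 difference was then 0.77 ± 0.08 for Pou3f3, with that sign in 8 of 8 individuals, and 0.90 ± 0.17 for Nkx2-3, which had at most 5 counts per library in individuals 2, 4, 6 and 8 and so rests on the other 4. Dlx5 and Dlx6, genes of the mandibular arch, alternated opposite to Pou3f3 at 7 of 7 steps between neighbouring stages in both labels. Dlx6 measured 7.28 to 14.3 CPM in labelled upper individuals 1, 3, 5 and 7 and 3.11 to 4.20 CPM in the others. Jaw genes did not alternate by their jaw throughout. The maxillary genes Shox2 and Meis1 also ran opposite to Pou3f3, Shox2 at 6 of 7 steps in labelled upper and 7 of 7 in labelled lower and Meis1 at 7 of 7 and 4 of 7, while the mandibular gene Dlx4 did so at 7 of 7 and 2 of 7. Because these jaw genes alternated inside the labels, every direction given here is between libraries labelled upper and libraries labelled lower.

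**Figure D1:**
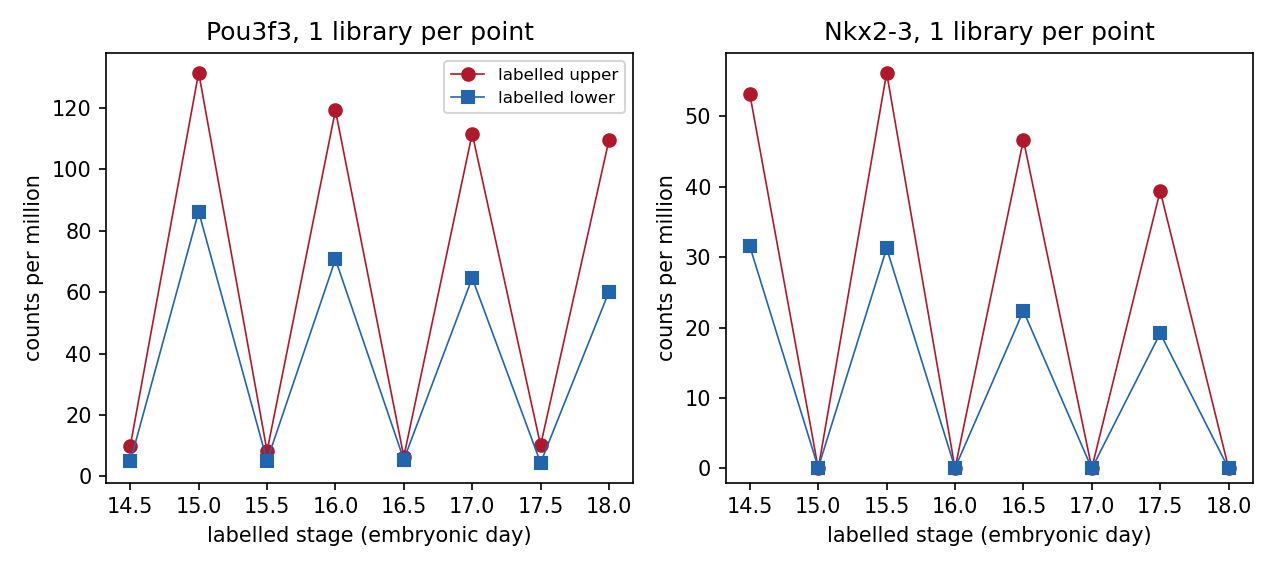
CPM of Pou3f3 (left) and Nkx2-3 (right) against the labelled stage in embryonic days, with 1 library per point, circles for libraries labelled upper and squares for libraries labelled lower. In both labels Pou3f3 is at 60.1 CPM or above in individuals 2, 4, 6 and 8 and at 10.1 CPM or below in the others, and Nkx2-3 runs the opposite way.

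The sex label did not match the counts either. Xist (chromosome X, 103460373 to 103483233), the RNA that coats the inactive X chromosome in female cells, measured 1499 to 1831 CPM in the libraries labelled upper and 431.8 to 1928 CPM in those labelled lower, although all were labelled male. The lowest values were 431.8 and 542.3 CPM, in labelled lower individuals 1 and 2. The labelled upper libraries of these individuals had 1664 and 1739 CPM, although the labels give both teeth the same embryo. The Y-linked genes Eif2s3y, Kdm5d and Uty had 0 counts in all 16 libraries and Ddx3y had 2, both in 1 library. Counts fell on 2 of 13 listed Y-linked genes, 3 in all, so that chromosome could take reads. Whether it was counted in full is not given in the sources used here.

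The first principal component of the 500 most variable genes held 57.6% of the variance and ran from -34.7 to -8.79 in the libraries labelled upper and from 5.54 to 36.9 in those labelled lower, so the labels did not overlap on it. It followed the labelled stage inside each label, with Pearson's r = 0.949 (exact permutation p = 0.000893, adjusted 0.00357) and Spearman's rho = 0.905 (p = 0.00456, adjusted 0.0182) over the 8 libraries labelled upper. Over the 8 labelled lower, r was 0.866 (exact permutation p = 0.00898, adjusted 0.018) and rho 0.809 (p = 0.0218, adjusted 0.0436). Without the 2 most extreme stages r was 0.959 and 0.819. The adjusted values cover 4 relations, of both components in both labels. The second component, with 10.2% of the variance, alternated with the same individuals as Pou3f3 in both labels. That leaves clusters of 4 libraries, so no pooled relation with stage is given for it and none could be tested inside a cluster. From the first to the last stage in labelled upper its scores ran from -13.0 to -7.00 in individuals 1, 3, 5 and 7 and from 3.39 to 17.1 in the others, and in labelled lower from -6.21 to -12.8 and from 12.0 to 6.93.

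**Figure D2:**
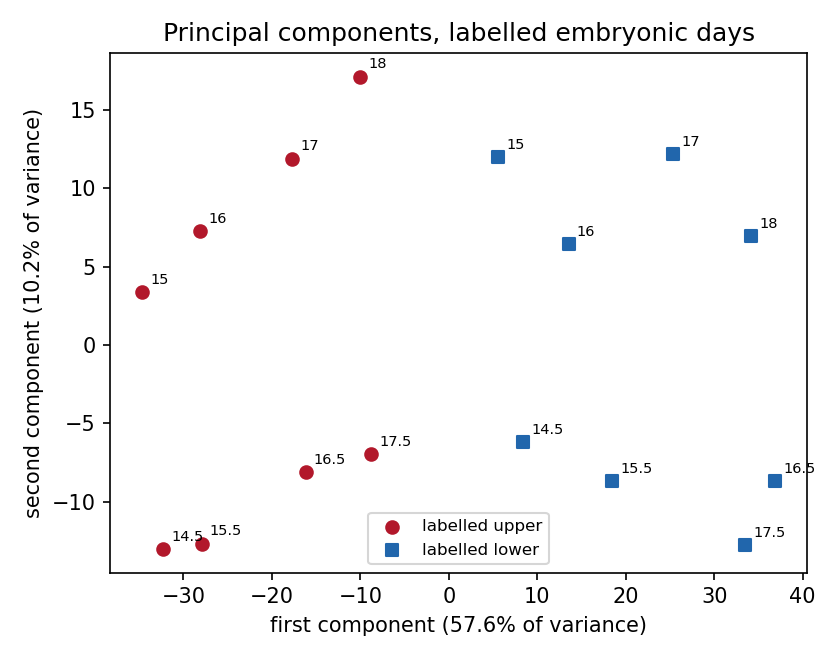
Scores of the 16 libraries on the first (57.6% of variance) and second (10.2%) principal components of log2 CPM, each point marked with its labelled embryonic day, circles for labelled upper and squares for labelled lower. The labels separate along the first component, from -34.7 to -8.79 against 5.54 to 36.9, and libraries of neighbouring labelled stages alternate along the second.

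Embryonic globin genes led the genes higher in the libraries labelled upper. Hbb-y (chromosome 7, 103851754 to 103853207), an embryonic beta globin, averaged 37.4 ± 39.2 CPM (SD, n = 8) in labelled upper and 0.495 ± 0.292 CPM in labelled lower, a log2 difference of 5.93 ± 0.43 (SE). Hba-x, an embryonic alpha globin, differed by 3.72 ± 0.27. A further 7 named genes of this direction differed by 2.31 to 3.15: Dmrt2, Cited1, Cyp26b1, B3gat1, Vgll3, Irs4 and Wnt2. Inside labelled upper Cited1, B3gat1 and Wnt2 alternated like Pou3f3 and Irs4 the opposite way. B3gat1 measured 1.09 to 2.82 CPM there in individuals 1, 3, 5 and 7 and 5.55 to 7.62 CPM in the others. Cyp26b1 (chromosome 6, 84571414 to 84593908), which degrades retinoic acid, averaged 85.3 ± 33.2 against 14.7 ± 5.75 CPM. Wnt2, a Wnt ligand, differed by 2.31 ± 0.73, and its call ended without individual 1 (adjusted p = 0.0533, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) or without individual 4 (0.0507). The other 8 named genes kept an adjusted p of at most 0.00264 with any individual left out by the same test.

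Crct1, Cnfn, Sprr3 and Plac8 had the largest differences in the other direction, with log2 values of -7.28 ± 1.12, -5.47 ± 0.62, -5.36 ± 0.64 and -5.36 ± 0.53. Crct1 had 4 counts over the 8 libraries labelled upper (exact 95% Poisson interval 1.09 to 10.2, counting error only), so the size of its difference is imprecise. In labelled lower it measured 0.0806 to 0.194 CPM in the first 4 stages and 1.98 to 10.4 CPM in the last 4, which ran on another lane. Cnfn (1.13 to 2.41 and 5.67 to 33.7 CPM) and Sprr3 (4.30 to 7.09 and 23.2 to 97.2 CPM) were split there too. Krt4, a keratin gene of stratified epithelium, averaged 106.8 ± 115 CPM (SD, n = 8) in labelled lower and 8.83 ± 14.2 CPM in labelled upper, a log2 difference of -4.04 ± 0.62. Both means lean on 1 library, since they were 3.83 ± 1.83 CPM (SD, n = 7) in labelled upper without individual 8 and 69.97 ± 53.3 CPM in labelled lower without individual 5. The oral cornifying epithelium list that holds it did not pass camera (adjusted p = 0.131, with 4 of 8 members higher in labelled lower). Tbx22 (chromosome X, 107667964 to 107688980), a T-box gene of the palate, averaged 13.2 ± 6.0 against 0.758 ± 0.901 CPM, a log2 difference of -4.37 ± 0.36, and 0.483 ± 0.492 CPM in labelled upper without individual 7. Psca, Ddn, Kcne1 and Igfbpl1 differed by -4.59 to -3.96. Igfbpl1 alternated opposite to Pou3f3 in labelled lower, at 43.5 to 111.4 CPM in individuals 1, 3, 5 and 7 and 15.8 to 52.7 CPM in the others. Psca and Ddn had 36 and 49 counts over the 8 libraries labelled upper. The adjusted p of these 10 genes lay between 1.51e-07 and 0.000378 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each had the same sign in 8 of 8 individuals. Over all 16287 genes, 2946 were higher in labelled upper and 2956 in labelled lower, of which 318 and 645 differed by over 2-fold. The flow cell follows the tooth label, so their parts could not be separated. A part of developmental stage could not be separated either, since the libraries labelled lower lay ahead on the shared stage trends described below. This holds for the gene lists that follow too.

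Osteoclast genes were higher in the libraries labelled lower at 11 of 11 members, 11 of them also when adjusted over the list alone and 10 with the individual as a block. Acp5, the tartrate-resistant phosphatase, differed by -1.65 ± 0.25 on the log2 scale, Atp6v0d2 by -1.25 ± 0.17, Dcstamp by -1.26 ± 0.19 and Mmp9 by -1.12 ± 0.18, and the list passed camera (adjusted p = 1.61e-05, but adjusted p = 0.376 with an estimated correlation). Enamel knot genes, active in the epithelial center that shapes cusps and including secreted signals, transcription factors and a receptor, had 10 of 18 members higher in labelled lower and 3 in labelled upper, 11 and 3 adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.52 with an estimated correlation). The individual as a block left 9 higher in labelled lower and 3 in labelled upper, and Bmp2 lost its call. Shh differed by -2.11 ± 0.20, Msx2 by -1.68 ± 0.11, Fgf9 by -1.39 ± 0.12 and Bmp7 by -0.91 ± 0.07. The Fgf pathway had 10 of 19 higher in labelled lower and 3 in labelled upper, the same numbers adjusted over the list alone, with Spry4 at -0.69 ± 0.06 and Fgf18 at 1.81 ± 0.27 (camera adjusted p = 0.0138, and adjusted p = 0.376 with an estimated correlation). Dental mesenchyme went the other way, with 10 of 21 higher in labelled upper and 2 in labelled lower, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.642 with an estimated correlation). The block gave 12 and 2 for this list. Msx1 differed by 1.22 ± 0.14, Postn by 1.12 ± 0.11, Prrx1 by 1.08 ± 0.11 and Zeb1 by -0.58 ± 0.07. Of 8 measured erythroid genes 4 were higher in labelled upper, 5 adjusted over the list alone (camera adjusted p = 0.00234, and adjusted p = 0.245 with an estimated correlation). The adult beta globin genes Hbb-b1 (0.06, adjusted p = 0.947) and Hbb-b2 (0.68, 0.182) and Alas2 (0.15, 0.468) did not pass edgeR's quasi-likelihood test. Slc4a1 did (0.95, 0.00013), as did the embryonic globins, so the difference was not shared by all erythroid genes.

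The jaw lists were mixed. Of 7 maxillary genes, Shox2 (1.01 ± 0.08), Meis2 (2.20 ± 0.23), Meis1 (0.75 ± 0.10) and Osr2 (0.44 ± 0.10) were higher in labelled upper and Tbx22 was higher in labelled lower, 4 and 1 also adjusted over the list alone. Pou3f3 (0.75 ± 0.85) and Sim2 (0.47 ± 0.32) did not pass. Pou3f3 did with the individual as a block. The list passed camera only with the individual as a block (adjusted p = 0.0264, against 0.0746 without the block, and adjusted p = 0.465 with the block and an estimated correlation). Of 8 measured mandibular genes, Dlx4 (-1.67 ± 0.13), Dlx5 (-1.24 ± 0.22) and Dlx6as1 (-2.18 ± 0.38) were higher in labelled lower, while Dlx6 (-0.90 ± 0.34), Gbx2 (-1.56 ± 0.67), Gsc (0.61 ± 0.42), Isl1 (1.65 ± 0.64) and Pitx1 (0.14 ± 0.19) did not pass. Adjusted over the list alone 5 were higher in labelled lower and 1 in labelled upper, and camera gave an adjusted p of 0.12. With the individual as a block Dlx6 was also higher in labelled lower and Isl1 in labelled upper (adjusted p = 0.00384 and 0.0361, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

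The other 21 lists did not pass camera for the labelled tooth difference, and their counts are given as higher in labelled upper, higher in labelled lower and measured. Ameloblast and enamel matrix genes had 0, 3 and 8, with Dlx3 at -1.16 ± 0.07 and Sp6 at -1.77 ± 0.14, odontoblast and dentin matrix genes 1, 4 and 11, bone and osteoblast genes 2, 4 and 7, and cartilage genes 2, 5 and 12. Mmp13, a collagenase, differed by -3.75 ± 0.34, Spp1 by -3.33 ± 0.43 and Hapln1 by -2.88 ± 0.20. Among other tissues, skeletal muscle had 1, 1 and 12, neuron 2, 3 and 10, Schwann cell 0, 0 and 8, endothelium 1, 4 and 10, macrophage and leukocyte 0, 7 and 12, oral cornifying epithelium 0, 4 and 8, and dental epithelium 3, 5 and 20. Csf1r, the receptor of a macrophage growth factor, differed by -0.84 ± 0.16. Among pathways, Wnt had 8, 12 and 30, Bmp 5, 10 and 19, Hedgehog 6, 3 and 11, Eda 5, 2 and 9, Notch 3, 6 and 14, and activin and Tgfb 3, 1 and 14. Rspo3, which amplifies Wnt signaling, differed by 2.30 ± 0.14 and its relative Rspo2 by -1.57 ± 0.18, while Id4, a Bmp target, differed by -1.04 ± 0.05 and Hhip, a Hedgehog target, by -1.42 ± 0.14. Cell cycle had 1, 4 and 25, basement membrane 4, 8 and 19, immediate early and heat shock 1, 4 and 15, and hypoxia and glycolysis 3, 3 and 12. Adjusted over the list alone, the numbers in labelled lower were 5 for odontoblast and dentin matrix and 6 for cartilage, those in labelled upper were 3 for bone and osteoblast and 5 for basement membrane, and the others were as given. With the individual as a block the first 2 numbers became 6 and 5 for dental epithelium, 1 and 4 for ameloblast and enamel matrix, 0 and 2 for Schwann cell and 2 and 8 for cell cycle. They moved by at most 2 for 7 others (odontoblast and dentin matrix, cartilage, neuron, Wnt, Bmp, Notch and basement membrane). For dental epithelium, skeletal muscle, Bmp and basement membrane the mean and the median had opposite signs.

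Some muscle genes rose and some cell cycle genes fell with labelled stage in the libraries labelled upper. Of 12 skeletal muscle genes 8 rose, 11 adjusted over the list alone, led by Actc1 at 1.66 ± 0.21 log2 per day, Myh3 at 1.48 ± 0.15 and Acta1 at 1.16 ± 0.19 (camera adjusted p = 1.04e-07, and adjusted p = 0.289 with an estimated correlation). Of 25 cell cycle genes 7 fell, 14 adjusted over the list alone, among them Ccnb2 at -0.20 ± 0.03 and Birc5 at -0.19 ± 0.04 (camera adjusted p = 6.68e-09, and adjusted p = 0.536 with an estimated correlation). Oral cornifying epithelium had 4 of 8 rising, 6 adjusted over the list alone, with Krt4 at 1.22 ± 0.23 and Krt1 at 0.54 ± 0.06 (camera adjusted p = 0.00026, and adjusted p = 0.289 with an estimated correlation). Macrophage and leukocyte genes had 2 of 12 rising, 7 adjusted over the list alone, with Lyz2, a lysozyme, at 0.50 ± 0.06 (camera adjusted p = 5.31e-05, and adjusted p = 0.289 with an estimated correlation). Erythroid genes had 4 of 8 falling, with Hbb-y at -1.33 ± 0.15 and Hba-x at -0.79 ± 0.13, and 4 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0421, and adjusted p = 0.392 with an estimated correlation).

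Basement membrane genes had 3 of 19 rising in labelled upper, among them Lama1 at 0.45 ± 0.05, and 5 rising with 1 falling adjusted over the list alone (camera adjusted p = 0.00224, and adjusted p = 0.468 with an estimated correlation). The Wnt pathway had 8 of 30 rising and 2 falling, 9 and 3 adjusted over the list alone, with Wif1 at 0.45 ± 0.06 and Rspo4 at -0.41 ± 0.05 (camera adjusted p = 0.0323, and adjusted p = 0.343 with an estimated correlation). Of 8 ameloblast and enamel matrix genes 1 rose, Dlx3 at 0.33 ± 0.03, and 3 did so adjusted over the list alone (camera adjusted p = 0.00549, and adjusted p = 0.289 with an estimated correlation). The other 20 lists did not pass. In all, 606 genes rose and 393 fell past the threshold, against 1161 and 890 with DESeq2's Wald test and 191 and 80 with a quadratic curve. An early/late step, which follows the sequencing lane, left 1 rising and 1 falling. Within a lane, which holds 4 libraries of a label, 0 genes passed in either lane, with 984 rising and 945 falling in the first and 523 and 437 in the second at an unadjusted p under 0.05 in edgeR's quasi-likelihood test. Of the 999 genes called over all stages, 947 and 931 had the same sign there. Without individual 1 there were 139 rising and 62 falling, without individual 2 there were 259 and 110, without individual 8 there were 137 and 55, without both 1 and 2 there were 15 and 3, and the falling number was 235 without individual 6 and 654 without individual 7.

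Few members of the cartilage and enamel lists rose in the libraries labelled lower. Acan, the large cartilage proteoglycan, rose at 0.68 ± 0.09 log2 per day and its partner Hapln1 at 0.55 ± 0.08, 2 of 12 cartilage genes and 3 adjusted over the list alone (camera adjusted p = 0.0453, and adjusted p = 0.509 with an estimated correlation). Enam, an enamel matrix protein gene, rose at 0.81 ± 0.14 and Dlx3 at 0.17 ± 0.02, 2 of 8 ameloblast and enamel matrix genes and 4 adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.577 with an estimated correlation). Basement membrane genes had 3 of 19 rising and 2 falling, 10 and 2 adjusted over the list alone, with Nid1 at 0.14 ± 0.03 and Col4a6 at -0.32 ± 0.04 (camera adjusted p = 0.00659, and adjusted p = 0.577 with an estimated correlation). The Bmp pathway had 2 of 19 rising and 1 falling, 5 and 2 adjusted over the list alone, with Id4 at 0.20 ± 0.02 (camera adjusted p = 0.0453, and adjusted p = 0.577 with an estimated correlation). Of 25 cell cycle genes Mcm7 fell, at -0.10 ± 0.02, the same number adjusted over the list alone (camera adjusted p = 6.89e-05, and adjusted p = 0.713 with an estimated correlation).

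Of 8 erythroid genes Alas2, the heme synthesis enzyme, fell at -0.26 ± 0.06 in labelled lower, and 3 did so adjusted over the list alone (camera adjusted p = 0.00659, and adjusted p = 0.509 with an estimated correlation). Odontoblast and dentin matrix genes and osteoclast genes had 0 of 11 members past the gene-wise test and 0 adjusted over the list alone, while camera gave both an adjusted p of 0.0423 (adjusted p = 0.577 and adjusted p = 0.73 with an estimated correlation). Their median slopes were 0.10 and 0.14. The other 20 lists did not pass. In all, 428 genes rose and 242 fell, against 1014 and 785 with DESeq2's Wald test and 57 and 15 with a quadratic curve. The early/late step left 16 rising and 3 falling. Within a lane 0 genes passed in either, with 831 rising and 784 falling in the first and 1071 and 992 in the second at an unadjusted p under 0.05 in edgeR's quasi-likelihood test, and 642 and 649 of the 670 genes had the same sign there. Without individual 1 there were 30 and 4, without 2 there were 177 and 64, without 6 there were 279 and 146, without 7 there were 147 and 39, without 8 there were 65 and 12, without both 1 and 2 there were 1 and 0, and the falling number was 158 without 3 and 134 without 4. In that fit without both 1 and 2, 1344 rising and 1358 falling genes had an unadjusted p under 0.05 in edgeR's quasi-likelihood test.

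Genes that trended in both labels were mostly alike in direction. Of 114 such genes, 106 had the same sign, with 86 rising where independent lists would share 15.9 and 20 falling where they would share 5.84. The labels pair the teeth of an embryo, so the lists need not be independent and deviations of an embryo could raise the overlap. Sall3 (chromosome 18, 80966989 to 80987021), a zinc finger transcription factor gene, rose at 1.39 ± 0.23 log2 per day in labelled upper and 0.41 ± 0.03 in labelled lower, and its call held with any individual left out. In the first lane of labelled upper alone the slopes of Sall3 (-0.10), Sp9 (-0.24) and Bcl2l12 (0.022) had the opposite sign and did not pass. The others of the 10 steepest rising genes were C4b, a complement component, Tbx22, Col19a1, Sp9, A2m, Sez6l, Pi15, Sall1 and Dio2, which activates thyroid hormone. Igf2bp1 (chromosome 11, 95957163 to 96005944), an RNA-binding protein of embryonic tissues, fell at -0.26 ± 0.02 in labelled upper and -0.25 ± 0.06 in labelled lower. Has2, which makes hyaluronan, fell at -0.24 ± 0.03 and -0.41 ± 0.08, and Stk32b at -0.32 ± 0.07 and -0.33 ± 0.06, and Tfap2c, Hs6st2, Psat1, Bcl2l12, Mgat4a and Heatr3 were among the 10 steepest falling genes too. Few of these calls were stable, since 5 of the 20 genes in labelled upper (Sall3, Sez6l, Has2, Igf2bp1 and Psat1) and 2 of 20 in labelled lower (Sall3 and Pi15) passed with each individual left out in turn. Across all genes, which are not independent replicates, the slopes of the labels correlated at r = 0.207 and rho = 0.310.

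**Figure D3:**
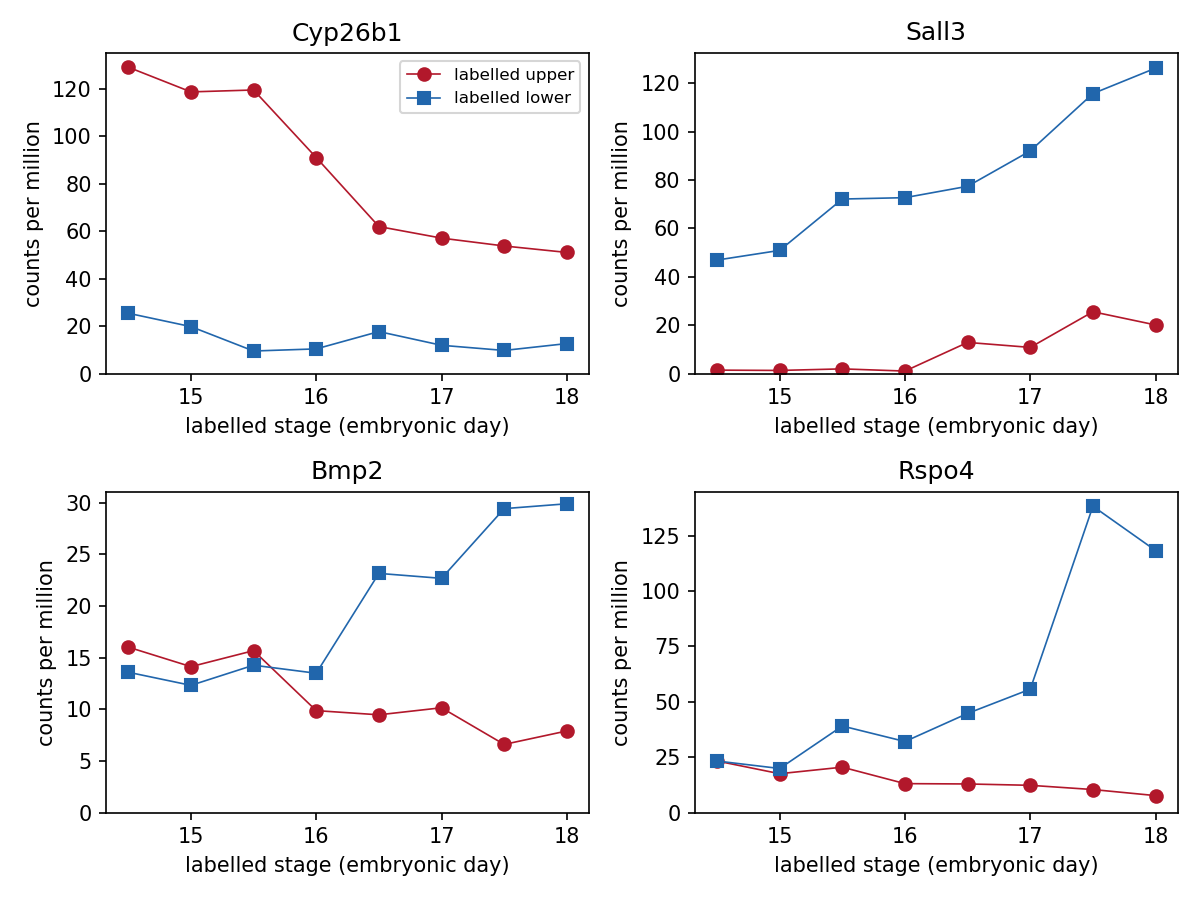
CPM of Cyp26b1, Sall3, Bmp2 and Rspo4 against the labelled stage in embryonic days, with 1 library per point, circles for labelled upper and squares for labelled lower. Sall3 runs from 1.53 to 20.2 CPM between the first and last stage labelled upper and from 47.0 to 126.2 CPM in labelled lower, while Rspo4 runs from 23.3 to 7.66 and from 23.3 to 118.3 CPM.

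Some signaling genes ran in opposite directions in the labels. Whether that belongs to the tooth could not be told, since the libraries labelled lower also lay ahead on the shared stage trends described below. Bmp2 (chromosome 2, 133552159 to 133562896), a secreted signal of the enamel knot, fell at -0.35 ± 0.06 log2 per day in labelled upper and rose at 0.41 ± 0.06 in labelled lower, a difference of -0.76 ± 0.09. Rspo4 (chromosome 2, 151842647 to 151874668), a Wnt amplifier, fell at -0.41 ± 0.05 and rose at 0.79 ± 0.10, a difference of -1.20 ± 0.13. Smoc2 (chromosome 17, 14279490 to 14404790), a matricellular protein gene, rose at 0.40 ± 0.06 and fell at -0.22 ± 0.03, a difference of 0.62 ± 0.07. The slope was higher in labelled upper also for Pdlim3 (1.35 ± 0.14), Rasgrf2 (0.91 ± 0.10), Lamc3 (0.38 ± 0.05) and Hist1h4i (0.67 ± 0.09), and lower for Tspan15 (-0.38 ± 0.04), Trim12c (-0.77 ± 0.09) and Chordc1 (-0.45 ± 0.06). The adjusted p of the 10 genes was 0.00209 to 0.00716 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and without individual 1 the calls of Lamc3, Hist1h4i and Chordc1 ended (adjusted p = 0.0711, 0.0711 and 0.0613 in the same test).

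Skeletal muscle had the higher slope in labelled upper as a list, with 0 of 12 members past the gene-wise test, 2 with the individual as a block and 5 adjusted over the list alone (camera adjusted p = 7.98e-05, and adjusted p = 0.857 with an estimated correlation). Cell cycle had the lower slope there, with 0 of 25 past, 5 with the individual as a block and 1 adjusted over the list alone (camera adjusted p = 0.000587, and adjusted p = 0.996 with an estimated correlation). The Eda pathway had 2 of 9 higher in labelled upper, Ctgf at 0.28 ± 0.04 and Tnfrsf19 at 0.16 ± 0.03, and 3 adjusted over the list alone (camera adjusted p = 0.00271, and adjusted p = 0.306 with an estimated correlation). The Wnt pathway had Wif1 higher at 0.35 ± 0.07 and Rspo4 lower, of 30, and 6 higher with 1 lower adjusted over the list alone (camera adjusted p = 0.0305, and adjusted p = 0.306 with an estimated correlation). The other 24 lists did not pass. In all, 111 genes had the higher slope in labelled upper and 98 in labelled lower. There were 279 and 196 with the individual as a block and 305 and 290 with DESeq2's Wald test. Without individual 1 there were 8 and 6, without 2 there were 31 and 23, without 3 there were 71 and 62, without 4 there were 71 and 57, without 5 there were 51 and 51, without 6 there were 68 and 68, without 7 there were 45 and 39, and without 8 there were 25 and 14. Without both 1 and 2 there were 0 and 0, with 705 and 629 at an unadjusted p under 0.05 in edgeR's quasi-likelihood test.

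The libraries labelled lower lay ahead of those labelled upper on the shared stage trends. Of 99 genes that trended alike in both labels and also differed between the labels, all 83 rising genes were higher in labelled lower and all 16 falling genes were higher in labelled upper. Over the 106 genes that trended alike, the offset of labelled upper minus labelled lower was -3.92 ± 0.42 days (SD, n = 8), with a range of -4.41 to -3.22 days and the same sign in 8 of 8 individuals (exact two-sided sign-flip permutation p = 0.00781, the smallest it can give). The span of the labelled stages was 3.5 days, and the flow cell differs between the labels here too.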

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

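The comparison of library neighbours was chosen before those distances were computed, although component scores had been seen, and the comparisons of the calls with other splits were also chosen before. The other tests of the jaw markers, the offset and Xist were chosen only after the result was seen. Each expression value was set against the other libraries of its label, and chance alone puts about 1 in 20 such groups of 8 that far apart. Of 119 groups, 4 held a library far from the others: Irs4 at 1.32 CPM in labelled lower individual 1, Cnfn at 0.512 CPM in labelled upper individual 5, and Krt4 at 43.8 CPM in labelled upper individual 8 and at 364.2 CPM in labelled lower individual 5. The named slopes with the smallest p for a difference between the labels, 5 in each direction, differed as upper minus lower in log2 per day for Pdlim3 (1.35), Smoc2 (0.62), Rasgrf2 (0.91), Lamc3 (0.38), Hist1h4i (0.67), Rspo4 (-1.20), Tspan15 (-0.38), Trim12c (-0.77), Bmp2 (-0.76) and Chordc1 (-0.45).

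Pou3f3 and Nkx2-3 alternated between libraries inside each tooth label, and Dlx5 and Dlx6 did so opposite to Pou3f3 at 7 of 7 steps in both labels, as did the maxillary gene Shox2 at 6 and 7 of 7, so the alternation does not sort all jaw genes by jaw. Whether germs of both jaws were mixed in a library stays open. In individuals 2, 4, 6 and 8 the highest Nkx2-3 value was 0.585% of the lowest in the other individuals, so little Nkx2-3 RNA of such germs was present. Nkx2-3 was chosen after this alternation was seen and lies outside the jaw lists, so it cannot decide the mixing of jaws. In the others the highest Pou3f3 value was 16.9% of the lowest high one, and its level in an unmixed germ is not known here. A candidate explanation is that labels and files were joined in a different order: if successive library codes in the file names are the 2 germs of an embryo, the 8 such neighbours should lie closer over all genes than the 7 neighbours between them. Their root mean square distances were 0.414 ± 0.039 and 0.520 ± 0.032 log2 (SD), and 0.647 ± 0.028 for the 8 labelled pairs (exact one-sided permutation p = 0.000155, the smallest it can give; 0.00202 with the 4 between-pair neighbours of the same lane). Labelled pairs lay at 0.607 or more and neighbours of either kind at 0.572 or less, but labelled pairs also differ in flow cell. Xist was low in labelled lower individuals 1 and 2, which have successive codes, at 431.8 and 542.3 CPM. Their labelled upper partners had 1664 and 1739 CPM, and labelled lower individuals 3 and 4 of the same lane 1754 and 1928 CPM. That argues against the labelled pairing for individuals 1 and 2 alone. The order was found and tested on the same libraries, so it remains a hypothesis, and no library was regrouped. Between the labels Dlx4, Dlx5, Meis1, Meis2 and Shox2 went with the labelled jaw in 8 of 8 individuals. Tbx22 went against it in 8 of 8. These differences cannot decide it, because under that order the labels would also differ in stage, and Tbx22 rose with labelled stage in both.

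The libraries labelled lower lay about 3.92 labelled days ahead on the shared trends, more than the 3.5 labelled days that the stages span. An effect of the flow cell stays open. Across the 106 genes the label difference correlated with the slopes measured inside flow cells at -0.896, but the offset was drawn from these same values. The slopes also follow the lane inside each flow cell, so the correlation cannot decide it. A lead of lower over upper molars, the biological explanation that the design gives, stays open for the offset and was not tested. Such a lead would not by itself give the alternation of Pou3f3 and Nkx2-3 between neighbouring stages inside both labels. Nor would it by itself change the globin RNA of blood, which both germs of an embryo share. Hbb-y measured 3.035 to 102.2 CPM in labelled upper and 0.1057 to 0.9104 CPM in labelled lower. Hba-x measured 1.856 to 16.68 and 0.1999 to 0.8976 CPM. These values argue against a lead as the only difference between the labels, for these 2 genes alone. Jaw genes went both ways, with Dlx4 (-1.67) and Meis2 (2.20) in the direction of the labels and Tbx22 (-4.37) against it. A different order of labels and files would shift the labels by 8 steps of 0.5 labelled days. The offset of -3.92 labelled days, with a range that includes -4, may reflect that. In that case the slopes per day and the offset would not be in true embryonic days, and each label would hold germs of both jaws. The label difference and the interaction would then set earlier against later stages, and not upper against lower molars.

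Xist was present in all 16 libraries labelled male, at no less than 431.8 CPM, with 2 counts of 4 Y-linked genes in total. Counts fell on 2 of 13 listed Y-linked genes, 3 in all, so Y-linked reads were not left out altogether. Whether that chromosome was counted in full is not given in the sources used here. Maternal tissue among male germs is argued against by the 2 counts as far as Y-linked reads were counted, since male cells would keep Y-linked RNA. Germs of the other sex than labelled may account for both values.

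Chance assignment of libraries is argued against for the numbers of calls of the labelled tooth difference and the slopes, but not by every test for the interaction. For the labelled tooth difference, 1 of 100 splits of the 16 libraries gave as many genes, the real one with 5902, and the highest other gave 30. Among 100 swaps of the labels inside pairs it was again 1, and the highest other gave 2134; the 5 others with 1129 calls or more each swapped a single pair, so they stay close to the real labels. For the interaction 1 of 100 splits gave as many, the real one with 209 against 5, but such splits leave the tooth difference in the scatter. With the individuals reordered in the interaction term alone 2 of 100 orders gave as many, and the highest other, with 364, placed each even-numbered individual after its odd-numbered neighbours. Among 100 swaps inside pairs 6 gave as many, and the highest other gave 3810. The 5 others swapped 2 to 4 individuals, mostly from one end of the stages, so the tooth difference may enter their slopes, and chance is not excluded by this test. For the slopes 1 of 100 orders of the stages gave as many in each label, with 999 against 616 in labelled upper and 670 against 50 in labelled lower. The other splits and orders leave a real label or stage difference in the scatter, which lowers their calls. They test chance and not whether a label names the right tooth or whether a slope follows the lane.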

How the results depend on the processing

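The fits without individuals 1 and 2 and within a lane were chosen after seeing the data, and the others before. Of the results called, 3 reversed, all in the first lane of labelled upper alone: the slopes of Sall3 (-0.10), Sp9 (-0.24) and Bcl2l12 (0.022). The labelled tooth difference stayed within 1.5 times its counts under every alternative except a test against a fold of 1.5, which left 206 genes higher in labelled upper and 509 in labelled lower, since that test asks for more. The individual as a block gave 3051 and 3071, with 5565 of the 5902 genes shared, 337 lost and 557 added. The 20 named genes kept their call under the block, and of 378 list memberships 4 lost it and 24 gained it. No camera call other than that of the maxillary list changed. Some lists that were not called turned direction, the neuron list for the tooth difference (adjusted p = 0.653 and 0.888) and the neuron, bone, maxillary and mandibular lists for the interaction. For the slopes (rising and falling), DESeq2 gave 1161 and 890 in labelled upper and 1014 and 785 in labelled lower, the early/late step 1 and 1 and then 16 and 3, the quadratic curve 191 and 80 and then 57 and 15, leaving out individuals 1 and 2 gave 15 and 3 and then 1 and 0, and each lane alone, with 4 libraries, 0 and 0 in both labels by edgeR's test. Leaving out 1 individual gave 137 to 747 rising and 55 to 654 falling in labelled upper, and 30 to 473 and 4 to 285 in labelled lower. For the interaction (higher slope in labelled upper and in labelled lower), DESeq2 gave 305 and 290, the block 279 and 196, leaving out individuals 1 and 2 gave 0 and 0, and leaving out 1 individual 8 to 71 and 6 to 68. Fewer libraries and an added term lower the power, and the cause was otherwise not tested. With an estimated correlation 0 lists passed camera in each comparison, against 5, 8, 8 and 4, while 2, 4, 2 and 2 had an unadjusted p under 0.05. The offset stayed between -3.997 and -3.793 days; no gene passed an adjusted p of 0.001 in both labels, so that alternative gave no value. The first component held 44.3% over all genes. Named genes kept their call in 423 of the fits that left out an individual and lost it in 137, and in 398 and 168 of the other fits, in the same direction except for the 3 slopes named. Depth limits genes near the cutoff of 0.269 CPM, which rests on 10 counts.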

Other observations

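Some genes chosen after their values were seen differed in level between the labels, with little or no overlap. Hmga2, a chromatin protein gene of embryonic growth, measured 200.2 to 489.2 CPM in the 8 libraries labelled upper and 104.7 to 218.7 CPM in the 8 labelled lower. Igf2bp1 measured 61.8 to 118.3 and 28.1 to 61.0 CPM. Shh, the signal of the enamel knot and inner enamel epithelium, ran the other way, at 42.8 to 146.5 and 180.8 to 602.2 CPM, and so did Mmp13, at 0.644 to 18.1 and 38.1 to 175.2 CPM. Hand1 and Hand2, genes of the distal mandibular arch, had 5 and 7 counts in total in the libraries labelled lower and 0 and 9 in those labelled upper.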
